A study of Allium cepa with 42 samples.

How the data were processed

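RNA from onion bulbs was measured on custom 60-base oligonucleotide arrays in 1 colour. Per the labels' protocols, 4 bulbs were taken for each treatment and time, 2 lengthwise wedges of each were frozen, and total RNA was extracted with a CTAB buffer. Cy3-labelled cRNA was made from 0.5 µg of RNA. Lengthwise wedges can hold more than one tissue, and tissue make-up was not measured. Samples were put into 14 groups by the cultivar, stage and curing temperature in their labels, with 3 samples in each, and bulbs at harvest had no curing temperature.

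The scanner files hold a fluorescence intensity per spot, which per the file headers was measured with Agilent Feature Extraction 10.5.1 on a single array, background-subtracted and detrended, and not normalised between arrays. Raw median intensity of each spot and of its local background is in the same files, per the file headers. Each file has flags for spots well above background, saturated or outlying. The table that the authors deposited for the whole series holds log2 values. Its normalisation is not given in the sources used here, but each column matched the scanner values after quantile normalisation and centring of each probe on its median, at a correlation of 0.9998 to 1.0000. This comparison fixed its scale, centring and direction. Its column medians lay between -0.116 and 0.131. The files of the 8 arrays of slide 1 have 26 columns and lack the mean spot signal that the other files have. The files carry slide and scan day, and the 42 arrays lay on 8 slides scanned on 5 days.

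Of the spots on an array, 15200 carried onion probes and 536 were controls, which were left out. The onion spots held 13310 probes, of which 18 were spotted 106 times each. Spots of a probe were averaged on the log2 scale. Where well above background, those repeats had a mean SD of 0.102 within an array, outlier spots left out. This gives the technical precision of such probes on 1 array, and not that of dim probes. Outlier flags removed all spots of a probe in 386 cases, 241 of them among tested probes. Saturated spots were to be kept, but no onion spot was flagged as saturated. Values are log2 of the processed signal minus the 75th percentile of the array. A probe was tested if it was well above background in all 3 samples of at least 1 group, which held for 9613 probes, or 72.2%. Dim arrays limited what could be measured: 1704 probes were well above background on all 42 arrays, and the 75th percentile of the signal ran from 4.42 to 1606. The correlation between samples of a group ran from 0.639 to 0.982, with a median of 0.902. Of the tested probes, 50 pairs shared a sequence, and their curing changes correlated at 0.990.

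Tests were run with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on all 42 samples with 1 mean per group and 28 residual degrees of freedom, Benjamini-Hochberg adjustment within a comparison, and a threshold of 0.05 on the adjusted p. The 19 comparisons were 3 storage steps, 3 curing temperature differences, 5 cultivar differences and 8 interactions. Each step was averaged over cultivars and temperatures. Groups, tests, filter and most of the other settings were fixed before the data were examined. Probes were named by the part of that rule meant for arrays without annotation: the 2 rising and the 2 falling probes with the largest change. The rule did not say whether untested changes count, and it was read as covering probes past the threshold, so comparisons without calls name none. Figures were drawn with matplotlib 3.10.9.

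Other settings chosen beforehand were quantile normalisation, median centring, normexp background correction (offset 50) followed by quantile normalisation, the authors' table, no filter on dim probes, probes well above background on all arrays, and replicate number, slide, scan day or file format as a block. The groups of a comparison alone, array weights, and leaving out each array in turn were also planned. Normexp was run on the median spot signal, which all files share. Array weights were estimated gene by gene because the default method stopped before it converged. Alternatives chosen after the data were seen were the percentile over probes detected on all arrays, leaving out slide 1, leaving out 4 arrays with raised weak spike-in signals (ratio to a strong spike-in above 0.001), slide as a block with quantile normalisation, and slide 1 alone. Fits without 1 slide at a time, set against the difference inside that slide, were also chosen then, so that no array entered both sides. So was a test that took the 96 probes with the lowest p between cultivars on slides 1, 2, 3 and 8 and read their direction on slides 4, 6 and 7.

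The scripts were tested on simulated data, with 9374 probes without missing values and 100 probes changed at each of 2 sizes. Noise was drawn independently for each probe and array, at the probe's spread around its group means on the real arrays. No slide effect or correlation between probes was put in. The recovery and false calls below therefore do not show how the tests behave under the slide differences of the real arrays. At a log2 change of 2, 68% of the changed probes were recovered for curing, 81% for early cold storage, 80% for sprouting, 43% for curing temperature after curing and 91% for cultivar over all stages. At a log2 change of 1 these were 9%, 23%, 22%, 6% and 43%. The shares at a log2 change of 2 with slide as a block were 0%, 26%, 24%, 0% and 94%. False calls numbered 0 to 9.

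No gene list was tested. The 34 lists fixed beforehand needed an annotation text, and 0 of them matched the descriptions in the files, so gene names and pathways were not analysed here.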

Results

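RNA abundance was measured in bulbs of onion (Allium cepa) from 2 brown-skinned cultivars, the long-storing Wellington and the average-storing Sherpa, at 4 stages: freshly harvested, after 6 weeks of curing, in cold storage at 1 °C before sprouting (presprouting), and sprouting in that cold storage. Curing, a warm drying of the outer skins and neck of the bulb before storage, was done at 20 or 28 °C. This gave 14 groups of 3 samples, 42 arrays in all: 6 at harvest and 12 at each of the later stages. The submitters describe the 3 samples of a group as biological replicates. They took 4 bulbs per treatment and time, and how those bulbs were shared between replicates is not given in the sources used here, so the p-values measure the spread between these samples.

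Each array carried 13310 different probes of 60 bases, read in 1 colour (Cy3), and 9613 of them were bright enough in at least 1 group to be tested. The share of probes well above background, which takes the place of sequencing depth on an array, ran from 16.5% to 89.3%. It had a median of 75.2% at harvest, 45.8% after curing, 40.2% at presprouting and 36.1% at sprouting. The stages were spread unevenly over the glass slides, so these medians do not measure an effect of stage alone. The 8 arrays of slide 1, which carried 5 of the 6 harvest samples and 3 samples cured at 20 °C, detected 71.5% to 80.3% of the probes. Another 4 arrays, on which weak spike-in controls were also raised, detected 77.1% to 89.3%, and the other 30 detected 16.5% to 55.2%. The number of arrays limits the precision of every value given here. The files pair no probe with a gene name, so probes are given by their IDs, and some by their sequence.

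**Figure D1:**
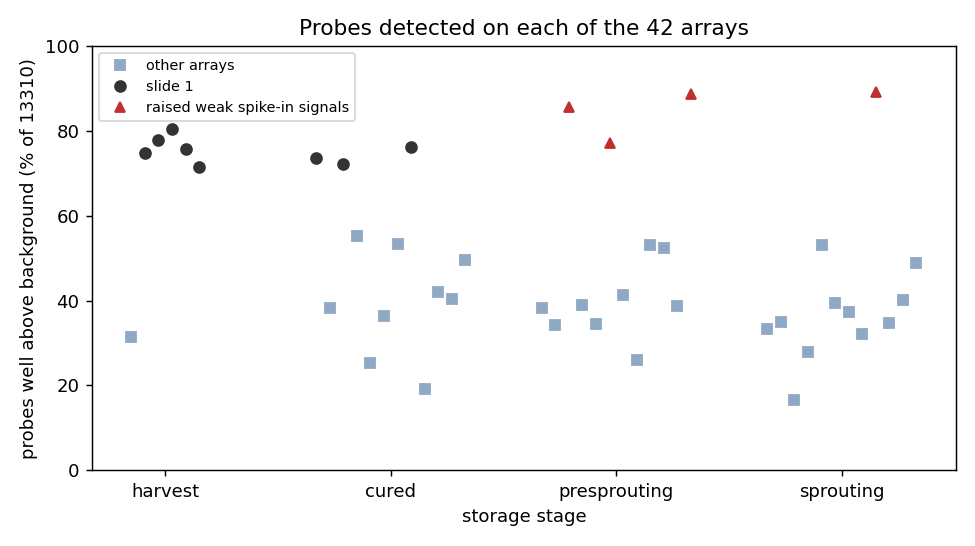
Percentage of the 13310 probes well above background (vertical axis) on each of the 42 arrays, by storage stage (horizontal axis); each point is 1 array and is marked as slide 1, as having raised weak spike-in signals, or as neither. The 5 harvest arrays of slide 1 lie at or above 71.5%, while the harvest array on another slide is at 31.3%.

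Stage accounted for a median of 21.7% of a probe's variance over the 42 samples, against a median of 5.96% for 4 groups of random numbers. Cultivar accounted for 0.961%, against 1.15% for random numbers, and curing temperature for 4.58% among the 36 samples taken after harvest, against 1.35%. Slide accounted for 40.3%, against 16.0% for random numbers in 8 groups. On the first principal component, which held 42.8% of the variance, differences between slides made up 80.7% and differences between stages 49.4%, shares that overlap because stages were spread unevenly over slides. That component also had a Spearman correlation of 0.690 with the 75th percentile of the array's signal.

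The first comparison asked which transcripts differed after curing. CUST_617_PI403527117 fell by 5.58 ± 0.89 (log2 change ± SE), from 2.75 ± 1.51 (mean ± SD, n = 6) at harvest to -2.83 ± 2.21 (n = 12) in cured bulbs, where 4 of 12 arrays measured it well above background. CUST_2333_PI403527117 fell by 5.48 ± 0.81, from 1.78 ± 1.32 (n = 6) to -3.70 ± 2.20 (n = 12), where 1 of 12 arrays measured it well above background, and all 12 cured samples lay below all 6 harvest samples for both probes. Their limma adjusted p were 0.000174 and 8.6e-05. No fold is given for probes that most arrays of a group did not measure, since it rests largely on signals near background. Of the rising probes, CUST_10790_PI403527117 was not well above background on any harvest array. It rose to -0.89 ± 2.47 (n = 12) after curing (limma adjusted p 0.000188). For the means over all harvest and all cured arrays, the bound on its rise was 14.2-fold. Such a bound sets the brighter group's mean against, on each dim array, the higher of the probe's own signal and the lowest signal of any probe well above background. CUST_10851_PI403527117 rose by 5.40 ± 1.00 (42.4-fold, adjusted p 0.000763), from -3.70 ± 3.23 (n = 6, 4 of them well above background) to 1.70 ± 2.63 (n = 12). Normexp background correction with an offset, followed by quantile normalisation, gave smaller changes: -2.96, -2.19, 1.12 and 1.93 in the order given. For CUST_10790_PI403527117 the normexp change lies below the bound, as do the log2 changes with quantile normalisation (3.81) and with slide as a block (2.67). Its log2 differences inside slides 1 and 5 (2.98 and 3.29) lie below it too. The bound thus describes the means over all arrays and is no lower limit on the change with curing. After this scaling, signals near background read lower on brighter arrays. Undetected at harvest, CUST_10790_PI403527117 read -8.07 on Wellington replicate 1, where the 75th percentile was 496. On Sherpa replicate 1, where it was 16.6, the probe read -3.20.

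In all, 1240 probes differed between cured and harvested bulbs in the limma fit at an adjusted p under 0.05, of which 809 rose and 431 fell, and 1221 changed at least 2-fold. For probes near background these changes also carry the difference in brightness between arrays. The direction of 1000 of the 1240 was the same in each of the 4 combinations of cultivar and curing temperature. The calls were made on the average of these combinations, so part of this agreement is built in. Tested by temperature, 2688 probes differed between harvest and bulbs cured at 28 °C and 65 between harvest and bulbs cured at 20 °C. By cultivar, Sherpa alone gave 20 calls and Wellington alone 878. These counts also differ in slide: all Wellington harvest arrays lay on slide 1, while Sherpa harvest replicate 1 lay on slide 5. In the limma test of the cultivar by curing interaction 0 probes passed, and 150 had an unadjusted p under 0.05, where chance alone gives 481. The counts therefore do not show a larger response in Wellington. With slide as a block 13 probes passed, all falling, 12 of them among the 1240; 956 of the 1240 kept their direction, and the median absolute change of the 1240 went from 1.83 (median SE 0.51) to 0.74 (median SE 0.87). CUST_2333_PI403527117 still passed with that block (log2 change -7.35, adjusted p 0.00973) but not when quantile normalisation was added to it (-5.33, 0.0766), while CUST_617_PI403527117 (-5.09, 0.274), CUST_10790_PI403527117 (2.67, 0.952) and CUST_10851_PI403527117 (2.08, 0.999) did not. A fit without slide 5, which held 1 array of each stage (harvest of Sherpa, cured of Wellington, so that cultivar differs too), called 2425 probes, and 40.8% of them differed within slide 5 in the direction of that fit, against 43.6% of all tested probes. No fit without slide 1 was possible. The log2 differences within slides 1 and 5 were -8.12 and -5.44 for CUST_617_PI403527117, -8.32 and -6.02 for CUST_2333_PI403527117, 2.98 and 3.29 for CUST_10790_PI403527117, and 2.43 and 0.48 for CUST_10851_PI403527117.

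The balance of rises and falls after curing also moved with the scaling. Rises made up 65.2% of the calls with each array scaled to its 75th percentile, and quantile normalisation gave 971 rising and 1008 falling probes, or 49.1% rising. Median centring gave 229 rising and 194 falling. The percentile taken over probes detected on all 42 arrays gave 363 and 1458, and background correction by normexp with quantile normalisation 929 and 1137. Quantile normalisation moved the median change of all probes from -0.07 to -0.22. Single arrays moved the count too. It was 2873 without Sherpa harvest replicate 1, which is the harvest array outside slide 1, 318 without Sherpa harvest replicate 2 and 290 without Sherpa harvest replicate 3. It was 655, 511 and 592 without Wellington harvest replicates 1, 2 and 3, 665 without Sherpa cured at 20 °C replicate 2, and 783 and 2006 without Wellington cured at 20 °C replicates 1 and 2. The 4 named probes passed in each of the 18 fits that left out 1 array.

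The next comparison asked which transcripts differed between cured bulbs and bulbs in cold storage before sprouting. CUST_7598_PI403527117 (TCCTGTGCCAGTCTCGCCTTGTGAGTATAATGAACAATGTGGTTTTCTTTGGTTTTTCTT) rose by 8.30 ± 0.79 on the log2 scale, 315-fold, from 3.42 ± 2.46 in cured bulbs to 11.72 ± 1.08 at presprouting (n = 12 each, adjusted p 1.4e-09). CUST_3047_PI403527117 (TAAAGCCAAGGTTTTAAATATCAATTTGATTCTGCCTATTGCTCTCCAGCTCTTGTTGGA) rose by 7.25 ± 0.45, from -2.24 ± 0.96 to 5.01 ± 1.39 (adjusted p 1.2e-13). It was well above background on 4 of 12 cured arrays and on all 12 presprouting arrays. CUST_2054_PI403527117 fell by 4.49 ± 0.53 (adjusted p 1.0e-07), from 1.53 ± 1.23 to -2.96 ± 1.17, where 2 of 12 arrays measured it well above background, and CUST_9811_PI403527117 fell by 4.34 ± 0.64 (adjusted p 5.85e-06), from 1.38 ± 2.10 to -2.96 ± 1.13, where 3 of 12 did. With normexp the changes of the last 3 probes were 3.99, -1.96 and -1.81. For the first 3 of these probes all 12 presprouting samples lay outside the range of the cured samples.

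**Figure D2:**
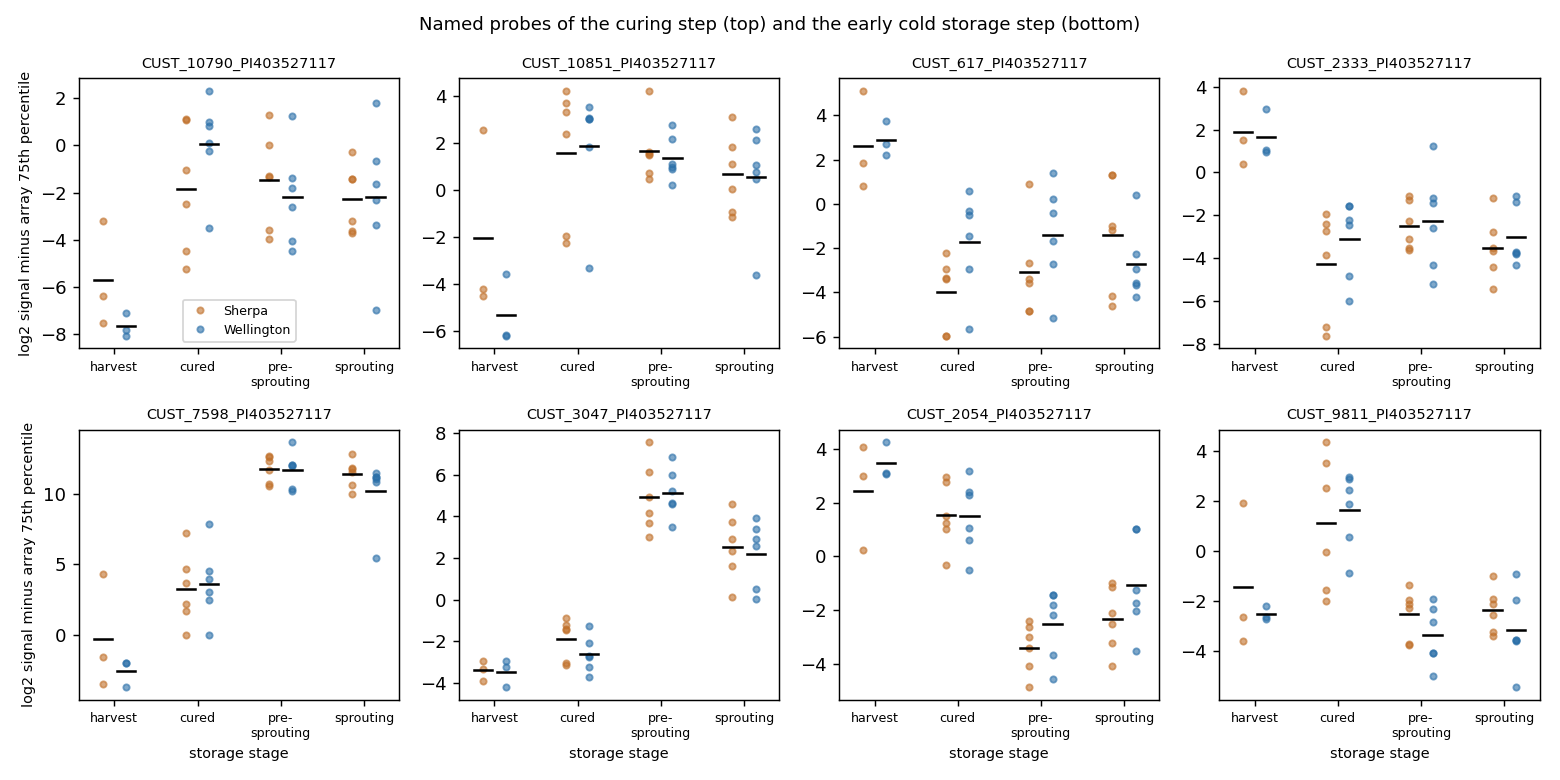
Normalised log2 signal (vertical axes, log2 signal minus the 75th percentile of the array; each panel has its own scale) of the 4 probes named for curing (top) and the 4 named for early cold storage (bottom) by stage (horizontal axes); each point is 1 sample and the bars are cultivar means (n = 3 at harvest, 6 at the later stages). CUST_7598_PI403527117 averaged 3.42 in cured and 11.72 in presprouting bulbs, with both cultivars at similar levels.

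In total 2329 probes differed between presprouting and cured bulbs (limma, 12 against 12 samples), with 1169 rising, 1160 falling and 1958 changed at least 2-fold. The direction was the same in all 4 combinations of cultivar and curing temperature for 2126 of them, which is again partly built in. Sherpa alone gave 1137 calls and Wellington alone 902. With slide as a block 782 probes passed (318 rising, 464 falling), 711 of them among the 2329, and 2325 of the 2329 kept their direction. The 4 named probes passed with that block, with changes of 7.84, 6.66, -3.74 and -5.71 in the order given and adjusted p between 3.6e-06 and 0.00473. A fit without slide 6, which held 2 arrays of each stage, called 2235 probes, of which 89.5% differed within slide 6 in the direction of that fit, against 67.0% of all tested probes. For slide 8, with 1 array of each, these values were 1764, 94.2% and 71.0%. Within these slides the 4 probes changed by 6.55 and 9.01 (CUST_7598_PI403527117), 7.34 and 8.71 (CUST_3047_PI403527117), -2.31 and -4.29 (CUST_2054_PI403527117), and -6.05 and -4.66 (CUST_9811_PI403527117). Median centring gave 921 rising and 582 falling probes, and the percentile over probes detected on all arrays 649 and 1138. Without slide 1 the count was 1267.

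From presprouting to sprouting, 2 probes passed, and both fell. CUST_3047_PI403527117, which had risen in early cold storage, fell by 2.63 ± 0.45 (6.20-fold lower, limma adjusted p 0.0123) to 2.38 ± 1.52 (n = 12). CUST_1011_PI403527117 (log2 change -2.06 ± 0.39, 4.17-fold lower, adjusted p 0.0389) fell from 0.29 ± 0.53 at presprouting, where all 12 arrays detected it, to -1.77 ± 0.85 at sprouting, where 7 of 12 did, and its change with normexp was -0.69. CUST_7598_PI403527117 averaged 10.80 ± 1.83 (n = 12) at sprouting and was not among the calls. At an unadjusted p under 0.05, 773 probes differed, where chance alone gives 481.

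None passed with slide as a block (limma, 436 at an unadjusted p under 0.05): the change of CUST_3047_PI403527117 was -3.54 (adjusted p 0.106) and that of CUST_1011_PI403527117 was -1.91 (0.852). Inside slides 3, 6, 7 and 8, CUST_3047_PI403527117 differed by -1.39, -5.97, -1.54 and -3.43 and CUST_1011_PI403527117 by -2.06, -1.87, -1.99 and -1.47. Over all 9613 probes, which are not independent replicates, the difference in slides 6, 7 and 8 correlated at 0.39, -0.03 and -0.06 with the change in a fit without that slide. Median centring gave 0 calls (adjusted p 0.244 for CUST_3047_PI403527117 and 0.325 for CUST_1011_PI403527117). Quantile normalisation gave 10 calls, 1 of them rising, and the percentile over probes detected on all arrays 12, with 2 rising. Background correction by normexp gave 45, with 14 rising. Replicate number, scan day and file format as a block gave 10, 13 and 18, array weights 215, the authors' values 11, the groups compared alone 6, and no filter on dim probes 1. Leaving out 1 array left 0 calls without Wellington sprouting 20 °C replicate 1, where CUST_3047_PI403527117 reached an adjusted p of 0.0501. It gave 4 without Wellington presprouting 28 °C replicate 1, 5 without Sherpa sprouting 20 °C replicate 2 or Sherpa sprouting 28 °C replicate 2, and 6 without Sherpa sprouting 20 °C replicate 3. It gave 1 without any of Sherpa sprouting 20 °C replicate 1, Sherpa sprouting 28 °C replicate 1, Wellington sprouting 28 °C replicates 1, 2 and 3, Sherpa presprouting 20 °C replicates 1 and 2, Sherpa presprouting 28 °C replicate 1, Wellington presprouting 20 °C replicates 1 and 3, and Wellington presprouting 28 °C replicate 2. CUST_1011_PI403527117 missed the threshold in 16 of those 24 fits, with an adjusted p of at most 0.112.

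Curing temperature was compared at each stage, 28 °C minus 20 °C, with 6 samples at each temperature. No probe passed in the limma fit directly after curing, where 1850 had an unadjusted p under 0.05 against 481 by chance and the lowest adjusted p was 0.126. No probe passed at presprouting (139 unadjusted, below chance) or at sprouting (842 unadjusted). Quantile normalisation called 7 probes after curing, 0 at presprouting and 1 at sprouting, and its unadjusted counts were 1654, 235 and 420. After curing no slide carried samples of both temperatures, and with slide as a block 0 probes passed (132 unadjusted), with a median SE of 1.36 in place of 0.56. Left out singly, Sherpa cured at 20 °C replicate 2 raised the count after curing to 45 and Wellington cured at 20 °C replicate 3 raised it to 3. Array weights gave 2211. At presprouting, slides 4 and 6 carried both temperatures, and their differences over all probes correlated at -0.48 and -0.25 with those of a fit without that slide. At sprouting these correlations were 0.18 and 0.46 for slides 3 and 7. The slide block left 0 probes at either stage (493 and 1041 unadjusted). Quantile normalisation moved the median of all probes from -0.11 to 0.00 at presprouting and from -0.27 to 0.01 at sprouting.

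The cultivars were compared over all stages, 21 samples of each, to find transcripts that set the long-storing Wellington apart from Sherpa. CUST_8299_PI403527117 was lower in Wellington by a log2 difference of -4.42 ± 0.54 (limma adjusted p 5.2e-06). It was well above background in 17 of 21 Sherpa samples (mean -0.10 ± 2.00) and 1 of 21 Wellington samples (-4.53 ± 1.82). CUST_3475_PI403527117 was lower in Wellington by -4.05 ± 0.67 (16.6-fold, adjusted p 0.000437), at -1.97 ± 2.89 (12 of 21 samples well above background) against 2.08 ± 2.06. CUST_7055_PI403527117 was higher in Wellington by 2.39 ± 0.43 (adjusted p 0.00117), at -1.09 ± 1.47 (19 of 21) against -3.48 ± 1.89 (5 of 21). CUST_1022_PI403527117 was higher by 1.84 ± 0.35 (3.57-fold, adjusted p 0.00228), at 2.28 ± 1.48 against 0.44 ± 1.59. With normexp the differences were -1.12, -1.75, 0.70 and 1.05 in that order.

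**Figure D3:**
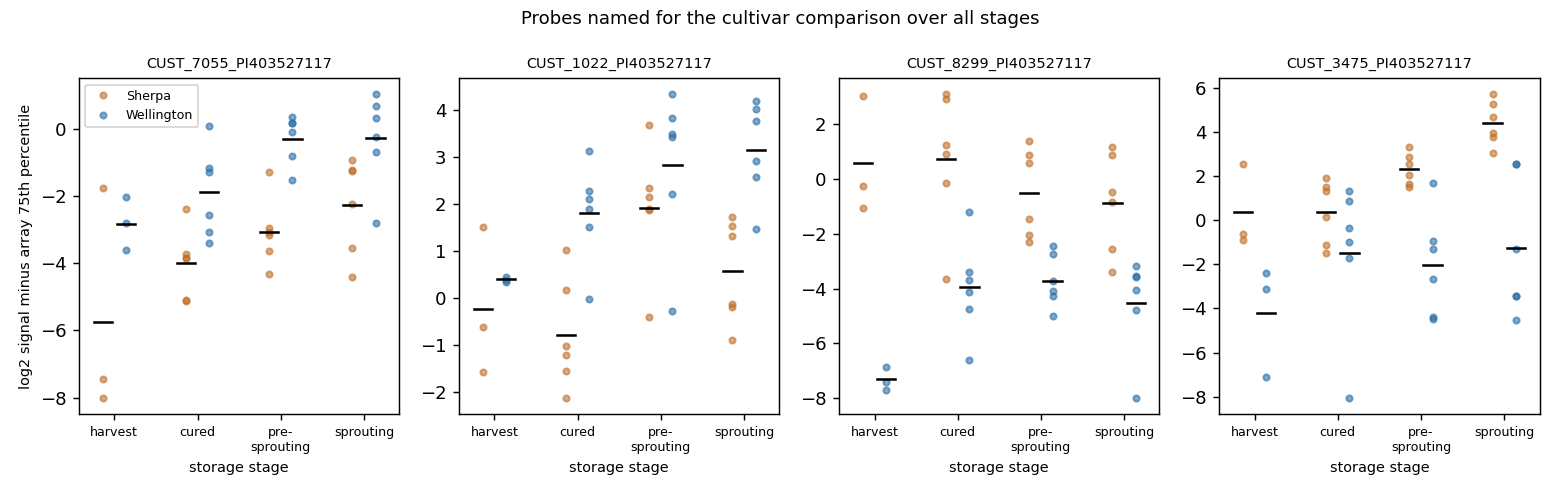
Normalised log2 signal (vertical axes, log2 signal minus the 75th percentile of the array; each panel has its own scale) of the probes named for the cultivar comparison over all stages (the 2 higher and the 2 lower in Wellington with the largest difference among those past the threshold), by stage (horizontal axes); each point is 1 sample and the bars are cultivar means (n = 3 at harvest, 6 at the later stages). CUST_8299_PI403527117 averaged -0.10 in Sherpa and -4.53 in Wellington.

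Over all stages 96 probes differed, 43 higher and 53 lower in Wellington, and 77 of them by at least 2-fold. The fit with slide as a block called 95 (30 higher, 65 lower), 66 of them shared, and all 96 kept their direction. The 4 named probes passed with it, at -4.30, -4.11, 2.14 and 1.87 in the order given and adjusted p between 5.9e-06 and 0.0110. Fits without slide 4, 5, 6 or 7 called 68, 73, 66 and 46 probes, of which 89.7%, 86.3%, 90.9% and 100% differed within the slide left out in the direction of the fit, against 47.5%, 61.6%, 43.9% and 54.3% of all tested probes. Slide 5 held 1 harvest array of Sherpa and 1 cured array of Wellington, so its share also reflects stage. Without slide 1, 2 or 3 no such fit was possible. Over the 7 slides that carried both cultivars, CUST_8299_PI403527117 (-6.71 to -2.25) and CUST_1022_PI403527117 (0.19 to 3.72) kept their sign on all 7. CUST_3475_PI403527117 was at 0.04 on slide 2 and between -5.59 and -1.25 on the other 6, and CUST_7055_PI403527117 was at -1.64 on slide 5 and between 1.94 and 3.23 on the other 6. Cultivar went with stage on slide 5, as given above. On slide 2 all Sherpa arrays were cured, while the Wellington arrays were cured and sprouting, so stage was not matched there either. Among the slides that carried both cultivars, stage was matched only on slide 4, where all arrays were presprouting. The differences and shares inside the other slides thus also reflect stage. Median centring gave 8 higher and 35 lower, and CUST_1022_PI403527117 then missed the threshold (log2 difference 1.82, adjusted p 0.0742).

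At harvest, with 3 samples of each cultivar, 3 probes passed, all lower in Wellington. CUST_8299_PI403527117 was not well above background in any Wellington harvest sample and averaged 0.57 ± 2.17 (n = 3) in Sherpa, at least 62.5-fold higher there (limma adjusted p 0.0252). CUST_9244_PI403527117 was likewise undetected in Wellington and averaged -1.44 ± 2.48 (n = 3) in Sherpa, at least 15.5-fold higher (adjusted p 0.0338). None passed with slide as a block (limma, 106 at an unadjusted p under 0.05), at -6.80 (adjusted p 0.0624) and -4.28 (0.214), and inside slide 1, with 3 Wellington and 2 Sherpa arrays, the differences were -6.65 and -4.22. Quantile normalisation called 5 higher and 2 lower, and normexp 17 and 1. The quantile step moved the median of all probes from -0.08 to 0.14, and neither named probe passed under it (log2 differences -4.75 and -3.01, adjusted p 0.363 and 0.480) or with normexp (-1.46 and -0.82, adjusted p 0.999 and 0.442). These differences lie below the bounds given, which hold only for scaling to the 75th percentile. Leaving out Sherpa harvest replicate 1, or Wellington harvest replicate 2 or 3, left 0 calls, and leaving out Sherpa harvest replicate 2 or Wellington harvest replicate 1 left 1.

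After curing 0 probes passed between cultivars in the limma fit (400 unadjusted), 0 with quantile normalisation and 6 with slide as a block, all lower in Wellington. Inside slides 1 and 6 the cultivar difference over all probes correlated at 0.21 and 0.24 with that of a fit without the slide. Quantile normalisation moved the median of all probes from 0.06 to -0.06. The count was 1 without Sherpa cured at 20 °C replicate 2 or replicate 3 and 2 without Wellington cured at 20 °C replicate 2. At presprouting 1 probe passed: CUST_53_PI403527117 was higher in Wellington by 2.78 ± 0.49 (6.89-fold, limma adjusted p 0.0236), at 2.85 ± 0.46 against 0.06 ± 0.94, and by 1.64 with normexp. In the fit with slide as a block it stood at 2.44 (adjusted p 0.293), a different probe passed, and inside slides 4 and 6 CUST_53_PI403527117 differed by 2.87 and 1.96. Quantile normalisation gave 3 higher and 2 lower, and normexp 3 and 1. The count at presprouting was 3 without Wellington 28 °C replicate 3, 2 without Sherpa 20 °C replicate 1, and 0 without any of Sherpa 20 °C replicates 2 and 3, Sherpa 28 °C replicate 3, Wellington 20 °C replicates 1, 2 and 3, and Wellington 28 °C replicates 1 and 2.

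At sprouting, 11 probes separated the cultivars (6 samples of each), 3 higher and 8 lower in Wellington. CUST_12199_PI403527117 differed by -4.41 ± 0.63 (21.2-fold lower, limma adjusted p 0.000464), at -1.88 ± 0.89 in Wellington, where 3 of 6 samples were well above background, and 2.53 ± 1.55 in Sherpa. CUST_8454_PI403527117 differed by -4.51 ± 0.75 (adjusted p 0.00223), at -2.66 ± 0.93 (2 of 6) against 1.85 ± 1.09. CUST_3449_PI403527117 was higher in Wellington by 2.44 ± 0.40 (5.44-fold, adjusted p 0.00223), at 3.49 ± 0.86 against 1.05 ± 0.92, and CUST_1121_PI403527117 by 2.32 ± 0.46 (4.98-fold, adjusted p 0.0305), at 1.21 ± 0.79 against -1.10 ± 1.28 (3 of 6). With normexp the differences of CUST_12199_PI403527117, CUST_8454_PI403527117 and CUST_1121_PI403527117 were -1.83, -1.70 and 1.03. The call of CUST_1121_PI403527117 was lost in 7 of 12 fits that left out 1 array (adjusted p up to 0.151), with no filter on dim probes (0.0620), with scan day as a block (0.0606), with median centring (0.254) and with the sprouting samples alone (0.440). That of CUST_3449_PI403527117 was lost with median centring (2.68, limma adjusted p 0.175) and with the sprouting samples alone (2.44, 0.267). For CUST_12199_PI403527117, CUST_8454_PI403527117 and CUST_3449_PI403527117 all 6 Wellington samples lay outside the Sherpa range.

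With slide as a block 5 of the 11 passed and no others, with CUST_12199_PI403527117 at -4.37 (adjusted p 0.00110), CUST_8454_PI403527117 at -4.40 (2.7e-05), CUST_3449_PI403527117 at 2.45 (0.0104) and CUST_1121_PI403527117 at 2.03 (0.206). A fit without slide 3 called 4 probes, 3 of which differed inside slide 3 in the direction of that fit, and a fit without slide 7 called 1, which did so inside slide 7. Inside slides 3 and 7 the differences were 2.00 and 2.31 for CUST_3449_PI403527117, 1.31 and 2.80 for CUST_1121_PI403527117, and between -5.83 and -2.96 for the 2 lower probes. Quantile normalisation gave 11 higher and 7 lower probes, normexp 9 and 6, median centring 0 and 2, and the percentile over probes detected on all arrays 7 and 5. Quantile normalisation moved the median of all probes from -0.24 to 0.06. The count fell to 6 without Sherpa 20 °C replicate 1, 5 without Sherpa 20 °C replicate 2, 4 without Sherpa 28 °C replicate 1, 7 and 5 without Wellington 20 °C replicates 1 and 2, and 3 without either of Wellington 28 °C replicates 2 and 3.

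Whether the storage steps or the temperature response differed between cultivars, and whether the temperature response differed between stages, was tested by 8 interactions in the same limma fit. No probe passed in any of them, with or without slide as a block or with quantile normalisation. At an unadjusted p under 0.05 the cultivar by step interactions gave 150 probes for curing, 467 for early cold storage and 265 for sprouting. The temperature by cultivar interactions gave 263 after curing, 438 at presprouting and 148 at sprouting. The temperature by step interactions gave 367 for early cold storage and 111 for sprouting, where chance alone gives 481. Their median SE on the log2 scale ran from 0.79 to 1.12, against 0.56 for the cultivar differences at single later stages. Interactions were thus estimated less precisely, and the size that could be detected was not simulated for them. Quantile normalisation moved the median of all probes most for temperature by cultivar after curing, from -0.53 to 0.20. Normexp called 6 probes for cultivar by curing and 5 for cultivar by early cold storage, and array weights 701 for temperature by cultivar after curing.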

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

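The spike-in, GC content, slide 1, separate slide, left-out array and split tests in this part were chosen only after the results they bear on were seen, while slide as a block was chosen beforehand.

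A signal outside the onion probes drew attention to 4 arrays. Of 2 weak spike-in controls, E1A_r60_3 had a median signal of 50.2 on these arrays (26.3 to 76.8) and 3.08 on the other 38 (1.89 to 20.9), a ratio of 16.3. E1A_r60_a104 had a median of 123 (65.2 to 166) against 4.45 (2.06 to 30.8), a ratio of 27.6. The arrays are replicate 3 of Wellington sprouting 20 °C, of Sherpa presprouting at 20 and at 28 °C, and of Wellington presprouting 28 °C. They were picked by the ratio of E1A_r60_3 to a strong control, and the signal of either weak control alone picks the same 4. They lie on slides 3 and 4, beside 8 arrays that were not raised, and detected 77.1% to 89.3% of the probes.

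More spike-in RNA is argued against as the source of the raised weak spike-in signals on the 4 arrays, since the strong control E1A_r60_n11 was no brighter there (ratio of medians 0.734). Storage stage or group is argued against too, since 0 of the 8 other arrays of these groups were raised. Nonspecific hybridisation stays open: on these 4 arrays the correlation of GC content with a probe's deviation from its group was 0.0994 to 0.216, inside the range of the other 38 arrays (-0.215 to 0.311). No biological explanation beyond the groups was tested.

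The curing calls were weighed against a slide difference, since slide 1 carried 5 of the 6 harvest arrays. For bulbs cured at 20 °C it is argued against as the whole cause: within slide 1, 3 cured and 5 harvest arrays gave 1329 calls (460 rising, 869 falling), 408 of them among the 1240 pooled calls. Over probes with no missing value the real split of these 8 arrays gave 1306 and the highest of its other splits gave 1 (56 splits in all). Slide 5, with 1 harvest array of Sherpa and 1 cured array of Wellington, did not bear the pooled step out: of 2425 probes called without it, 40.8% differed there in the same direction. For bulbs cured at 28 °C a slide difference cannot be told apart from curing, because no slide holds both: 2688 calls without a block became 0 with it. Curing itself may lie behind the changes seen inside slide 1. Those calls mostly fell, while the pooled calls mostly rose (809 of 1240). For the pooled calls beyond the 408 shared ones, slide 1 gives no such evidence, and they could still come from the slides.

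The early cold storage calls were weighed against a slide difference and against the 4 arrays. With slide as a block 782 probes passed, and the highest of the other splits of the stage labels under the same block gave 20 (100 splits in all), which argues against slide as the whole cause. Without the 4 arrays 2056 of the 2329 probes still passed in the same direction, which argues against those arrays as the cause. A change in transcript levels with cold storage is a candidate explanation; a change in the tissue make-up of the wedges and the time in store, which go with the stage, stay open and were not tested.

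Other splits of the same samples, drawn within the other factors, were fitted for each count. For early cold storage chance can be excluded: 1 of 100 splits, the real one, reached 2329 and the next gave 312. For curing 4 of 100 splits reached 1240. The highest, 3180, put all 8 arrays of slide 1 in one arm and points to slide as a structure of the samples. The count therefore also scores how slide 1 falls between the arms, and these splits do not exclude chance for curing. For sprouting 4 of 100 reached 2, and the highest, 1417, put the 4 arrays with raised spike-ins in one arm; with slide as a block the real count was 0. For the cultivars over all stages 6 of 100 splits reached 96, so this count alone does not exclude chance, and the highest, 2703, also put these 4 arrays in one arm. Under a slide block 4 of 100 splits reached its 95, and the highest other gave 396. On separate slides chance is argued against, but not excluded, as the source of the shared direction. The 96 probes with the lowest p on slides 1, 2, 3 and 8 were taken, which are not the 96 pooled calls. Only 3 probes passed the threshold on those slides. Of the 96 taken, 84 differed in the same direction on slides 4, 6 and 7. That many or more came from 4 of 400 assignments of cultivars within slide and stage, the real one included, with a highest other of 87. For the cultivars at sprouting 1 of 100 splits, the real one, reached 11 and the next gave 6. With slide as a block 7 of 100 reached the real 5 and the highest gave 1423. Chance is thus not excluded for the cultivar count at sprouting once slide is in the fit. At presprouting 5 of 100 reached the cultivar count of 1 (highest 1359, with 3 of the raised arrays in one arm), so chance cannot be excluded. At harvest the 10 splits are too few for a share under 0.05: the real count was 3 (1 of 10 splits) and the highest other 0.

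For the 12 comparisons with 0 calls the splits decide nothing, since every split reaches a count of 0 (100 of 100). Other splits gave at most 1141, 87 and 17 for temperature after curing, at presprouting and at sprouting, and 826 for the cultivars after curing. For cultivar by curing, early cold storage and sprouting they gave at most 701, 7 and 1311. For temperature by cultivar at the 3 stages the highest were 578, 1480 and 17, and for temperature by early cold storage and by sprouting 1486 and 2. The splits with the higher of these counts mostly gathered slide 1 arrays or raised arrays in one arm, which points to a structure of the samples.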

How the results depend on the processing

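The alternatives added after the data were seen were the percentile over probes detected on all arrays, leaving out slide 1, leaving out the 4 arrays with raised weak spike-ins, slide as a block with quantile normalisation, slide 1 alone, fits without 1 slide set against that slide, and the cultivar difference chosen on some slides and read on others; the others were planned. No named probe changed direction in any of these fits, but sizes moved. Inside single slides CUST_7055_PI403527117 (-1.64 on slide 5) and CUST_3475_PI403527117 (0.04 on slide 2) ran against the fit over all stages. Stage was not matched between the cultivars on these slides, nor on any other slide with both cultivars except slide 4. Normexp with an offset, followed by quantile normalisation, shrank the changes of all named probes but CUST_7598_PI403527117, CUST_3449_PI403527117 and the sprouting change of CUST_3047_PI403527117 by over 1.5 times. Examples were CUST_10790_PI403527117 from 5.80 to 1.12 and CUST_8299_PI403527117 over all stages from -4.42 to -1.12. Quantile normalisation alone gave 3.81 and -3.45 for these examples, so the shrinkage did not come from the background step alone. Scan day as a block gave CUST_10851_PI403527117 2.04 in place of 5.40 and CUST_2333_PI403527117 -8.35 in place of -5.48, and file format as a block gave CUST_10790_PI403527117 3.32 and CUST_10851_PI403527117 1.69. Neither of the rising probes CUST_10790_PI403527117 (limma adjusted p 0.171 with scan day, 0.127 with file format) and CUST_10851_PI403527117 (0.572 and 0.564) passed under these blocks. In slide 1 alone these rising probes changed by 2.98 and 2.15. The cold storage count stayed between 609 and 3830, and the count for cultivar over all stages between 11 and 662. Signal over background limits the rest: a probe undetected on every array of a group carries only a bound there. Where no reason is given, the cause was not tested.

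Quantile normalisation gave 1979 calls for curing, 10 for sprouting, 7 and 1 for temperature after curing and at sprouting, and 7, 5 and 18 for cultivar at harvest, presprouting and sprouting. The authors' value table gave 1975, 11, 5 and 1 for the first 4 of these, and 5 and 2 for cultivar at harvest and presprouting. Median centring gave 423 for curing, 1503 for early cold storage, 0 for sprouting, 43 for cultivar over all stages, and 0 and 2 for cultivar at presprouting and sprouting. Normexp gave 2066 for curing, 45 for sprouting, 1 for temperature after curing, 18 and 4 for cultivar at harvest and presprouting, and 6 and 5 for cultivar by curing and by early cold storage. Without a filter on dim probes, which tests 13310 probes, there were 2511 calls for curing, 1 for sprouting, and 0, 0 and 4 for cultivar at harvest, presprouting and sprouting. With only the 1704 probes detected on all arrays, fewer being tested, there were 674 for curing, 609 for early cold storage, 11 for cultivar over all stages, and 0 for cultivar at harvest and at sprouting.

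Slide as a block gave 13 for curing, 782 for early cold storage, 0 for sprouting, and 0, 6 and 5 for cultivar at harvest, after curing and at sprouting. Scan day as a block gave 52, 1420 and 13 for the 3 steps, 6 and 0 for cultivar after curing and at presprouting, and 5 for temperature by cultivar at presprouting. File format as a block gave 124 for curing, 18 for sprouting, 0 and 4 for cultivar at harvest and after curing, and 6 for temperature by cultivar at presprouting. The groups of a comparison alone gave 527 for curing, 6 for sprouting, and 0, 0 and 5 for cultivar at harvest, presprouting and sprouting. Array weights, estimated gene by gene, gave 6040, 3830 and 215 for the 3 steps, 2211 and 1 for temperature after curing and at presprouting, and 662 for cultivar over all stages. They gave 450, 41, 134 and 103 for cultivar from harvest to sprouting, 1 for cultivar by early cold storage, and 701, 8 and 1 for temperature by cultivar after curing, at presprouting and at sprouting.

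Of the added alternatives, the percentile over probes detected on all arrays gave 12 for sprouting, 1 for temperature after curing and 2 for cultivar after curing. Without slide 1 there were 1267 for early cold storage, 6 for sprouting and 0 for cultivar at presprouting. The curing step, the cultivar contrasts over all stages and at harvest, and cultivar by curing could not be estimated without slide 1. Without the 4 raised arrays there were 1 for sprouting, 6 for temperature after curing, and 1 and 0 for cultivar after curing and at presprouting. Slide as a block with quantile normalisation gave 10, 657 and 1 for the 3 steps, 1 for temperature at sprouting, and 0, 6, 2 and 5 for cultivar from harvest to sprouting. Slide 1 alone gave 1329 for curing, of which 460 rose and 869 fell, against 809 and 431 in the pooled fit, and 408 were shared.

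Leaving out 1 array at a time gave 290 to 2873 calls for curing, 1921 to 2535 for early cold storage, 0 to 6 for sprouting, 0 to 45 for temperature after curing, and 0 at the later stages. It gave 71 to 103 for cultivar over all stages, and 0 to 2, 0 to 2, 0 to 3 and 3 to 15 for cultivar from harvest to sprouting. All 8 interactions stayed at 0. Where an arm kept 2 arrays their spread was pooled with that of the other groups. Of the named probes, those for curing, early cold storage and cultivar over all stages passed in each such fit.

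Whether the shared replicate numbers pair the samples was not tested against chance. Deviations from the group means correlated at a mean of 0.056 for the same number and -0.027 for different numbers. Of 273 same-number pairs 110 lay above 0.1, and 20 of 42 samples matched their own number best. The 4 arrays with raised weak spike-ins were all replicate 3. With the replicate block the sprouting count was 10, and no other count moved by more than 1.5 times. The gene list alternatives (camera with a preset correlation, fry, and their other settings) were not run, since no list could be matched.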

Other observations

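The tests in this part were chosen after the values they concern were seen. Levels of the rising probes of early cold storage over all 4 stages were as follows: CUST_7598_PI403527117 averaged -1.45 ± 2.94 (SD, n = 6) at harvest, 3.42 ± 2.46 (n = 12) after curing, 11.72 ± 1.08 at presprouting and 10.80 ± 1.83 at sprouting (n = 12 each). CUST_3047_PI403527117 averaged -3.42 ± 0.52, -2.24 ± 0.96, 5.01 ± 1.39 and 2.38 ± 1.52 at these stages. It was well above background on 5 of 6 harvest and 4 of 12 cured arrays, so its cured mean rests largely on signals near background. Most harvest arrays lay on slide 1, so the harvest and cured means of either probe differ in slide as well as stage.

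It was asked whether curing changes turn back in cold storage. To keep the shared cured samples out, the curing change inside slide 1 was set against the cold storage change on the other arrays over 9374 probes, which are not independent replicates. The correlation was 0.0404 (Spearman 0.0411), and 43 of the 56 splits of the slide 1 arrays gave one as low, with the other splits between -0.145 and 0.123. No general reversal was seen. The cured arrays of slide 1 were all cured at 20 °C, while the cured arrays of the other slides came from both temperatures. The correlation that a real reversal would give was not established. Over these probes slide 1 alone gave 1306 curing calls, and the arrays outside slide 1 gave 1242 cold storage calls. Of these calls, 53 rose in both lists and 78 fell in both, where independent lists would share 29.0 and 58.3. Another 43 rose and then fell (30.7), and 73 fell and then rose (55.0).

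It was also asked whether the cultivar difference at harvest persists at sprouting. The differences correlated at 0.392 across the 9374 probes, but a two-sided permutation test that reassigned cultivars at sprouting gave p = 0.524 over 1000 assignments, the real one included. The question stays open.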
